A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

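The series holds 4 two-colour arrays of yeast deletion-strain tags, 1 for each combination of plasmid (cdc102-1 or wild-type CDC102) and temperature (28 or 30 degree). Per the labels, tags were amplified by PCR from genomic DNA and hybridised to a Hopkins tag array, images were read on a GenePix 4000B scanner and analysed with GenePix 5.1, and Cy5 marked the plates without Nat and Cy3 the Nat plates on every array, with no dye swap. The molecule field of the labels names RNA, but the description is of genomic DNA. Arrays were grouped by their titles, although the descriptions of both wild-type samples, after naming the wild-type plasmid, call the sporulated pool cdc102-1.

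The deposited values are log2 ratios of the 2 dyes for each spot. Every one of them was the log2 of a multiple of 0.01 within 0.1 percent, so the authors' ratios had been rounded to 0.01. The numerator, the background correction and any normalization between dyes are not given in the sources used here. Column medians of all deposited spots were -0.14, -0.17, -0.14 and -0.15 (cdc102-1 at 28 and 30 degree, CDC102 at 28 and 30 degree), so the columns had not been centred on 0. A stand-in ratio of 1000000 stood in 10 cells, which were left out. No spot intensities were used, so signal over background is unknown; rounding makes low ratios coarse, with 7, 33, 12 and 25 spots at a ratio of 0.01.

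Genes were taken from the platform's annotation of the probes. Of 22575 spots, 18794 had 1 gene symbol, 0 had several and 3781 had none. Of 5325 gene identifiers, 5321 were matched to the reference gene table (assembly R64), which also gave CDC102 as a synonym of PSF2 and the distances between genes. No build belongs to the arrays themselves, so no coordinates are printed. Spots with the same gene sat 10971 spot numbers apart in 2 blocks (100% of named spots in the first block had a partner of the same gene), taken as both tags of a strain. Which block holds uptags is not told, so they are called the first and the second tag. On the array, 793 strains had 6 or more spots per tag, and the other 4532 fewer; the median SD of those repeat spots was between 0.067 and 0.090.

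All spots of a strain were averaged within an array, and each array was centred on its median over the strains measured on all 4 arrays (5288 strains). The medians removed were -0.19, -0.27, -0.17 and -0.20. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with plasmid and temperature as additive terms over all 4 arrays and Benjamini-Hochberg adjustment at 0.05. It leaves 1 residual degree of freedom and assumes that the effect of the plasmid is the same at both temperatures; an effect that differs between temperatures enters the error. Comparisons at a single temperature have 1 array on each side and no test, and strains were counted there by a difference of at least 1 on the log2 scale. Gene lists were tested two-sided with camera at a preset correlation of 0.01, with an estimated correlation as an alternative, over 24 lists of 351 genes, 2 of them controls: auxotrophs, which the haploid selection should remove, and essential genes. The linkage check set the median of strains within 50 kb of CDC102 against all other windows of as many neighbouring strains.

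The strain test was run on simulated data: 5288 strains with the spread of the real fit, 200 of them shifted between plasmids, 50 at each size. At an adjusted p of 0.05 it recovered 0% of shifts of 1, 36% of shifts of 2, 84% of shifts of 3 and 88% of shifts of 4 on the log2 scale. At an unadjusted p under 0.05 it recovered 82%, 96%, 98% and 98%, against 4.82% of unshifted strains. A list of 9 strains shifted by 1 was recovered by camera at the preset correlation (adjusted p 3.62e-07), with 0 other lists called. The simulated noise was independent between strains, so this does not show how the list test performs where strains are correlated.

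The strains named were fixed by a rule before the data were examined: the 12 and 8 strains with the largest mean plasmid difference in each direction, and 5 in each direction for temperature, among strains past the test. As none passed, the places were filled by the absolute mean difference from strains with the same sign at both temperatures (or with both plasmids) and in both tags; strains within 100 kb of CDC102 were left out of the 12 and 8. PSF2, the 3 nearest measured strains on each side and up to 4 members of each list were named as well. The tag condition was read for the plasmid comparison within each temperature and for the temperature comparison within each plasmid.

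Alternatives were no centring, quantile normalization, the median over spots, each tag alone, strains whose tags differed by under 1, values on at least 3 arrays, leaving out the control lists or strains near CDC102, a robust prior, no second term, each array left out in turn (also without the second term, since 3 arrays with both terms leave no residual degrees of freedom), other windows and other size thresholds. Keeping the stand-in values, requiring both tags on every array, size counts without the control lists, and list tests by tag, on tag-agreeing strains, without each array and with an estimated correlation in the settings that gave calls were added after the data were examined.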

Results

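Barcoded deletion strains of budding yeast (Saccharomyces cerevisiae) were compared on 4 two-colour tag arrays in a screen for synthetic lethality with CDC102. CDC102 is a synonym of PSF2 (locus YJL072C, chromosome X), which encodes a subunit of the GINS complex, an essential part of the DNA replication machinery. Per the labels, a pool of 5896 heterozygous deletion strains had received a natMX disruption of chromosomal CDC102 and then a URA3 plasmid with either the cdc102-1 allele or wild-type CDC102. Titles and the plasmid named in each description assign 2 arrays to each plasmid, but a later sentence in the descriptions of both wild-type samples also names the cdc102-1 pool; the titles were followed. After sporulation, spores were grown for 2 days at 28 or 30 degree on plates lacking uracil, with or without nourseothricin (Nat), the drug that natMX confers resistance to. The Nat plates held haploids carrying both disruptions, and the plates without Nat held single and double mutants together. Strain tags amplified from genomic DNA of the plates without Nat carried Cy5, and those of the Nat plates carried Cy3. Each of the 4 combinations of plasmid and temperature was hybridised to 1 array, so no group had a replicate.

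The deposited value was a log2 ratio of both dyes for each of 22575 spots, of which 18794 named 1 gene, 0 named several and 3781 named none. Spots were averaged into 5325 strains, of which 5288 had a value on all 4 arrays. Each array was centred on its strain median, so a value of 0 is the median strain. Named spots without a value numbered 16 on the cdc102-1 array at 28 degree and 725 on that at 30 degree. On the CDC102 arrays they numbered 63 at 28 degree and 396 at 30 degree. The stand-in ratio stood in a further 0, 3, 3 and 4 spots, named or not, of these arrays in the same order. The SD over strains on these arrays was 0.73, 1.03, 0.65 and 0.77. Both tags of a strain correlated across strains with Pearson r of 0.476, 0.484, 0.349 and 0.296 in the same order (Spearman rho 0.522, 0.552, 0.416 and 0.381), where strains are not independent replicates. The SD of the halved difference between tags was 0.43, 0.57, 0.43 and 0.52. Any 2 arrays correlated across strains with Pearson r between 0.602 and 0.705. The number of arrays limits the precision of every comparison.

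The labels do not state which dye is the numerator of the deposited ratio. Cy5 over Cy3 is likely, because the labels list the Cy5 sample as source 1; on that reading a higher ratio means relatively less of a strain's tag from the Nat plates, that is, fewer double mutants. All values below are given as higher or lower deposited ratios.

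The comparison of the cdc102-1 with the CDC102 plasmid asks which gene deletions are recovered differently when the cell depends on the mutant allele. The largest mean differences belonged to GET1 and GET2, which encode the membrane receptor for insertion of tail-anchored proteins into the endoplasmic reticulum. The GET1 deletion had a ratio higher with cdc102-1 by 2.92 ± 0.36 (SE of the additive fit over 4 arrays) and the GET2 deletion by 2.69 ± 0.20. Their ratios with cdc102-1 were 3.15 and 3.40 at 28 degree and 4.20 and 3.51 at 30 degree, against 0.76 and 0.66, and 0.74 and 0.87, with CDC102. Deletions of several genes of Golgi and endosome traffic had higher ratios too: RIC1, which forms an exchange factor for the Golgi GTPase Ypt6, by 2.17 ± 0.33, from a mean of -1.17 with CDC102; MON2, a Golgi and endosome protein, by 1.88 ± 0.22; ARL1, a Golgi GTPase, by 1.82 ± 0.28; and NHX1, the endosomal sodium-proton exchanger, by 1.80 ± 0.27. The tags of NHX1 gave different sizes, 2.85 with the first tag only and 0.76 with the second, and RIC1 differed by 1.30 with the first tag only. No strain passed the limma test after Benjamini-Hochberg adjustment, so these are measured differences and not called changes.

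The other strains named as higher with cdc102-1 had mean differences of a similar size. The deletion of RPL17A, a ribosomal protein gene, had a ratio higher by 2.12 ± 0.24 and that of RVS161, an amphiphysin-like gene of endocytosis, by 2.10 ± 0.29. YAE1, an essential gene, had a difference of 2.02 ± 0.20, and TRP2, of tryptophan synthesis, 1.84 ± 0.24. Both of those deletions had ratios far below the median with CDC102 (means of -1.75 and -1.99). With the first tag only RVS161 differed by 1.33. NBP2, an adaptor of stress signalling, differed by 1.94 ± 0.33 and was close to the median with CDC102 (mean of 0.28). RRT12, a protease gene of spore wall formation, differed by 1.98 ± 0.62, with 3.05 at 28 degree and 0.91 at 30 degree.

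The 8 strains named as lower with cdc102-1 included several deletions of essential genes, for which no living haploid is expected on either plate. CDC43, a subunit of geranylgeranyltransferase, had a mean difference of -2.45 ± 0.78, and ALG2, a mannosyltransferase of N-glycosylation, one of -2.36 ± 0.61. At 30 degree the ratios of these strains with cdc102-1 were -4.71 and -4.87. The plasmid difference was -1.08 at 28 degree and -3.81 at 30 degree for CDC43, and -1.31 and -3.41 for ALG2. TIM12, of mitochondrial protein import, differed by -2.15 ± 0.23, MED6, of the Mediator complex, by -1.97 ± 0.49, DUO1, of the DASH complex at the kinetochore, by -1.83 ± 0.21 and EPL1, of the NuA4 acetyltransferase, by -1.81 ± 0.34. The remaining lower strains were deleted for the non-essential genes MUD1, of the U1 snRNP (-2.05 ± 0.21), and DPH5, of diphthamide synthesis (-1.83 ± 0.28). The first tag alone gave -1.17 for EPL1.

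**Figure D1:**
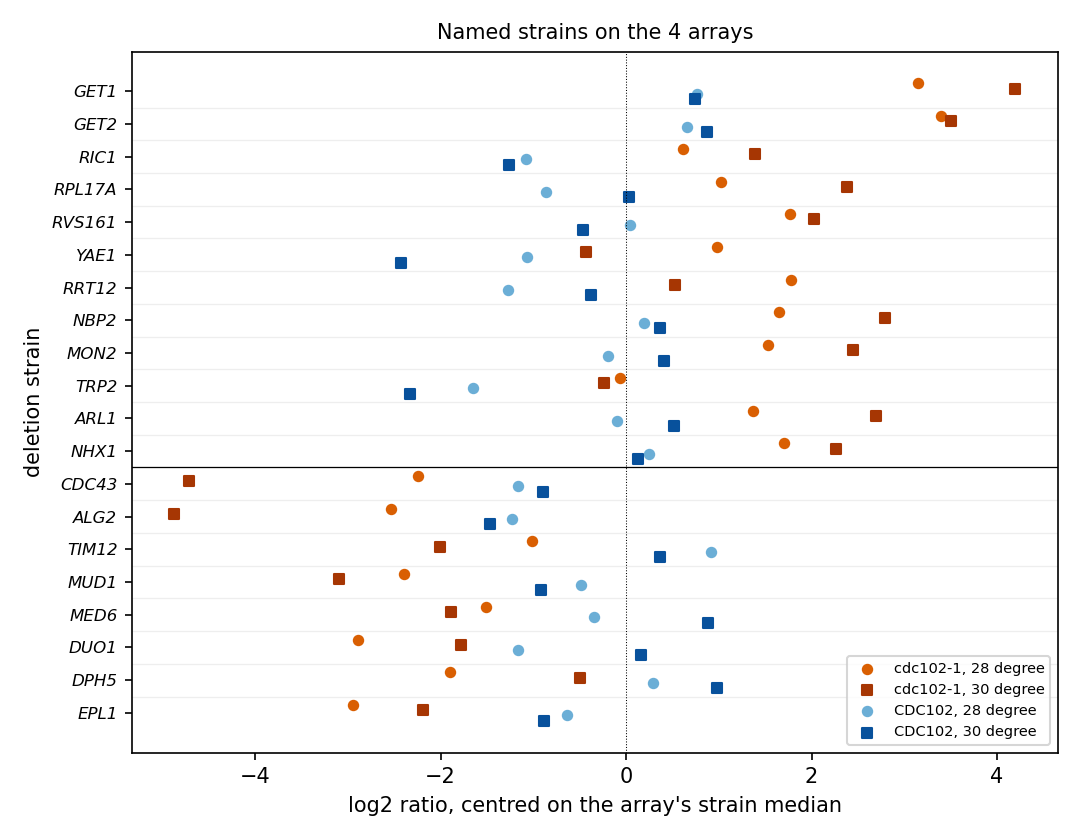
Centred log2 ratio (x axis) of the 20 named deletion strains (y axis) on each of the 4 arrays, with the 12 strains higher with cdc102-1 above the line and the 8 lower strains below it; each point is 1 array and there are no error bars. For GET1 the cdc102-1 arrays read 3.15 and 4.20 and the CDC102 arrays 0.76 and 0.74.

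In limma's test of the plasmid term, 0 of 5288 strains passed an adjusted p of 0.05, and the smallest adjusted p was 0.553. At an unadjusted p under 0.05 there were 462 strains, 283 higher and 179 lower, where chance alone gives 264.4. Fits to 3 arrays had to drop the temperature term to keep a residual degree of freedom, so their counts mix both factors; they ran from 197 without the CDC102 array at 30 degree to 878 without the cdc102-1 array at 28 degree. With all 4 arrays and no temperature term the count was 462 (279 higher and 183 lower). The test has 1 residual degree of freedom among arrays plus 2.30 borrowed across strains. No label describes separate cultures, so its p-values measure only the spread between these arrays, which may be technical.

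Counted by size alone, strains past the size at both temperatures were more often higher than lower with cdc102-1, while at 30 degree alone slightly more were lower. A ratio higher by at least 1 on the log2 scale was found for 208 strains at 28 degree and 411 at 30 degree, and 70 strains reached it at both; independent lists would share 16.2. A ratio lower by at least 1 was found for 150 and 419 strains, with 36 at both, against 11.9 for independent lists. The opposite pairs held 32 strains that were higher at 28 and lower at 30 degree and 16 with the reverse pattern, against 16.5 and 11.7 for independent lists, so opposite pairs were also more frequent than independence gives. Across strains, the differences at both temperatures correlated with Pearson r = 0.165 and Spearman rho = 0.221. Requiring each tag to pass the size at each temperature left 25 higher and 8 lower strains. Among those 25 were GET1, GET2, RIC1, MON2 and ARL1, and among those 8 were CDC43, ALG2, MUD1, DUO1 and DPH5. With 1 array per cell these counts have no test.

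**Figure D2:**
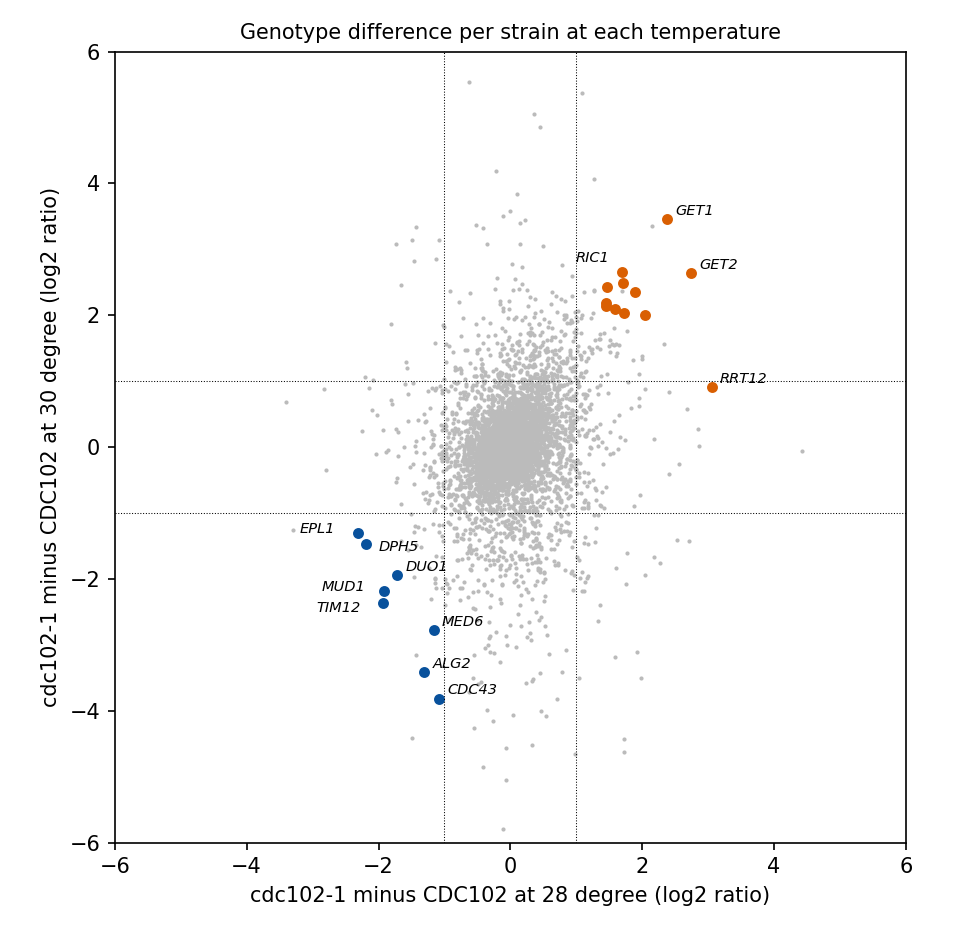
Difference in log2 ratio between the cdc102-1 and CDC102 pools at 28 degree (x axis) and at 30 degree (y axis); each grey point is 1 of 5288 strains, orange points are the 12 named higher strains, blue points the 8 named lower strains, and dotted lines mark differences of 1 and -1. GET1 lies at 2.38 and 3.46 and GET2 at 2.74 and 2.64, apart from the bulk of the strains, and 8 of the orange points are left unlabelled.

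Of the 24 gene lists fixed before the data were examined, the Swr1 complex, which places the histone variant H2A.Z into chromatin, had the highest mean difference between plasmids. Its 9 measured deletions averaged 0.64 ± 0.61 (SD over strains), with 5 higher and 0 lower at both temperatures. HTZ1, which encodes H2A.Z, differed by 1.40 ± 0.27 (SE), VPS71 by 1.34 ± 0.21, ARP6 by 1.00 ± 0.43 and SWC3 by 0.84 ± 0.54. HTZ1 and VPS71 were the 2 strains that passed when adjusted over the list alone, with a smallest adjusted p of 0.049 in limma, and 0 passed over all strains. By camera the list had an adjusted p of 0.056, and 0.804 with an estimated correlation. Its mean was 1.01 with the first tag only (adjusted p 0.00028), 0.85 on strains whose tags differed by under 1 on every array (adjusted p 0.0034), 0.48 with the second tag only (adjusted p 0.338) and 0.25 with quantile normalization (adjusted p 0.206). With an estimated correlation 0 lists passed with the first tag only (smallest adjusted p 0.787) or on those tag-agreeing strains (0.776).

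Other chromatin lists were higher in part. The list of COMPASS and H2B ubiquitination, which modify histone H3 and H2B, averaged 0.40 ± 0.42 over 10 strains, with LGE1 at 0.98 ± 0.25 and SWD1 at 0.78 ± 0.25. Its mean was 0.52 with the first tag only (adjusted p 0.023 at the preset correlation, and at least 0.787 at an estimated one), 0.24 with the second and 0.08 with quantile normalization. The Rtt101 ligase, H3K56 acetylation and histone assembly list averaged 0.35 ± 0.38 over 14 strains, 10 of them higher and 1 lower at both temperatures. Its largest values were those of MMS22 (1.15 ± 0.35), ASF1 (0.79 ± 0.21), RTT109 (0.65 ± 0.25) and HIR3 (0.65 ± 0.25). With CDC102 these strains averaged -0.10, -0.72, -0.54 and 0.23, and with cdc102-1 they averaged 1.05, 0.08, 0.11 and 0.88. ASF1 and RTT109 thus went from below the median strain to near it. SAGA and NuA4 averaged 0.15 ± 0.52 over 15 strains, with EAF7 and EAF5 higher by 0.91 ± 0.20 and 0.86 ± 0.21 and ADA2 at -0.84 ± 0.30; on strains whose tags differed by under 1 on every array its mean was 0.38 (adjusted p 0.035 at the preset correlation, and at least 0.776 at an estimated one). The histone deacetylase complexes averaged -0.20 ± 0.54 over 17 strains, and the Rpd3L subunits RXT2 and PHO23 had differences of -1.13 ± 0.20 and -1.04 ± 0.21. HDA2 of the same list was at 0.79 ± 0.24, and 4 of its strains were higher and 9 lower at both temperatures.

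Among the DNA repair lists, homologous recombination averaged 0.37 ± 0.38 over 9 strains, 6 of them higher and 1 lower at both temperatures. RAD57 differed by 1.11 ± 0.23, RAD52 by 0.65 ± 0.33, XRS2 by 0.45 ± 0.22 and MRE11 by 0.44 ± 0.20. RAD57, RAD52 and MRE11 lay below the median strain with CDC102 (means of -1.28, -0.35 and -0.42). With cdc102-1 they averaged -0.17, 0.30 and 0.02. XRS2 averaged 0.06 with CDC102 and 0.50 with cdc102-1. At 30 degree the tags of RAD57 gave differences of 0.15 and 1.66. Post-replication repair averaged 0.26 ± 0.31 over 9 strains, with RAD5 at 0.65 ± 0.20. The excision and mismatch repair list averaged -0.08 ± 0.51 over 19 strains, in which RAD4 had a difference of -1.43 ± 0.20 and its partner RAD23 one of 0.85 ± 0.20. The tag differences of RAD23 lay between 0.73 and 0.95. RAD4 did not have both tags measured on all 4 arrays, so its tags were not compared. The same held for RTT109, SWC3, SWD1, ADA2 and ERG4 of other lists. The list of Sgs1, Mus81 and Slx pathways averaged -0.07 ± 0.32 over 12 strains, with SLX8 at -0.64 ± 0.23. End joining and telomeres averaged -0.09 ± 0.66 over 9 strains, between NEJ1 at -1.46 ± 0.49 and EST2 at 1.07 ± 0.30.

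Lists closest to the replication fork lay near the median strain. The S-phase checkpoint averaged 0.08 ± 0.34 over 11 strains, and -0.01 with quantile normalization. Replisome-associated factors averaged 0.02 ± 0.36 over 13 strains, with RAD27, the flap endonuclease of lagging-strand synthesis, at -0.82 ± 0.20. Alternative clamp loaders and cohesion averaged -0.12 ± 0.42 over 7 strains, with CHL1 at -0.97 ± 0.49 and CTF4 at -0.18 ± 0.20. These members had no test result past the adjusted threshold.

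The mitotic lists had no common direction. The spindle checkpoint averaged 0.10 ± 0.35 over 5 strains, with a median of -0.05, and -0.09 with quantile normalization; BUB1 stood at 0.60 ± 0.38. The kinetochore list averaged -0.09 ± 0.60 over 10 strains, with 7 lower and 2 higher at both temperatures, and NKP2 at 1.54 ± 0.35. The list of tubulin folding and spindle motors averaged 0.14 ± 0.35 over 18 strains, with the prefoldin gene PFD1 at 1.15 ± 0.20. Dynein and dynactin averaged 0.08 ± 0.20 over 10 strains.

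Outside the nucleus, the cell wall and actin polarity list averaged 0.39 ± 0.70 over 18 strains, but its median was only 0.08. Of its strains, 10 were higher and 3 lower at both temperatures. RVS161 led the list, followed by SMI1 at 1.76 ± 0.50, RVS167, the partner of RVS161, at 1.03 ± 0.20 and the glucan-remodelling gene GAS1 at 0.97 ± 0.20. The difference of GAS1 came mostly from its first tag. Its tags gave 1.86 and 0.18 at 28 degree, and 1.60 and 0.23 at 30 degree. Ergosterol and drug efflux averaged 0.40 ± 0.70 over 8 strains, with ERG4 at 1.82 ± 0.36, ERG2 at 0.81 ± 0.26 and ERG6 at 0.59 ± 0.24. Heat and protein folding averaged 0.19 ± 0.25 over 15 strains, with SSA1 at 0.88 ± 0.20. The vacuolar ATPase averaged 0.04 ± 0.29 over 12 strains, and oxidative phosphorylation -0.12 ± 0.25 over 24 strains. The control list of auxotrophs averaged -0.25 ± 0.58 over 14 strains and that of essential genes 0.09 ± 0.66 over 56 strains.

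By camera with a preset correlation of 0.01, 0 of the 24 lists passed an adjusted p of 0.05 for the plasmid term. At an unadjusted p under 0.05 there were 5, namely Swr1, Rtt101 with H3K56 acetylation, homologous recombination, COMPASS and the cell wall list, with adjusted p between 0.056 and 0.072. With an estimated correlation there were 0, and the smallest adjusted p was 0.804. For the clamp loader list the mean (-0.12) and the test pointed down while the median was 0.03, and for the spindle checkpoint the mean and the test pointed up while the median lay below 0.

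**Figure D3:**
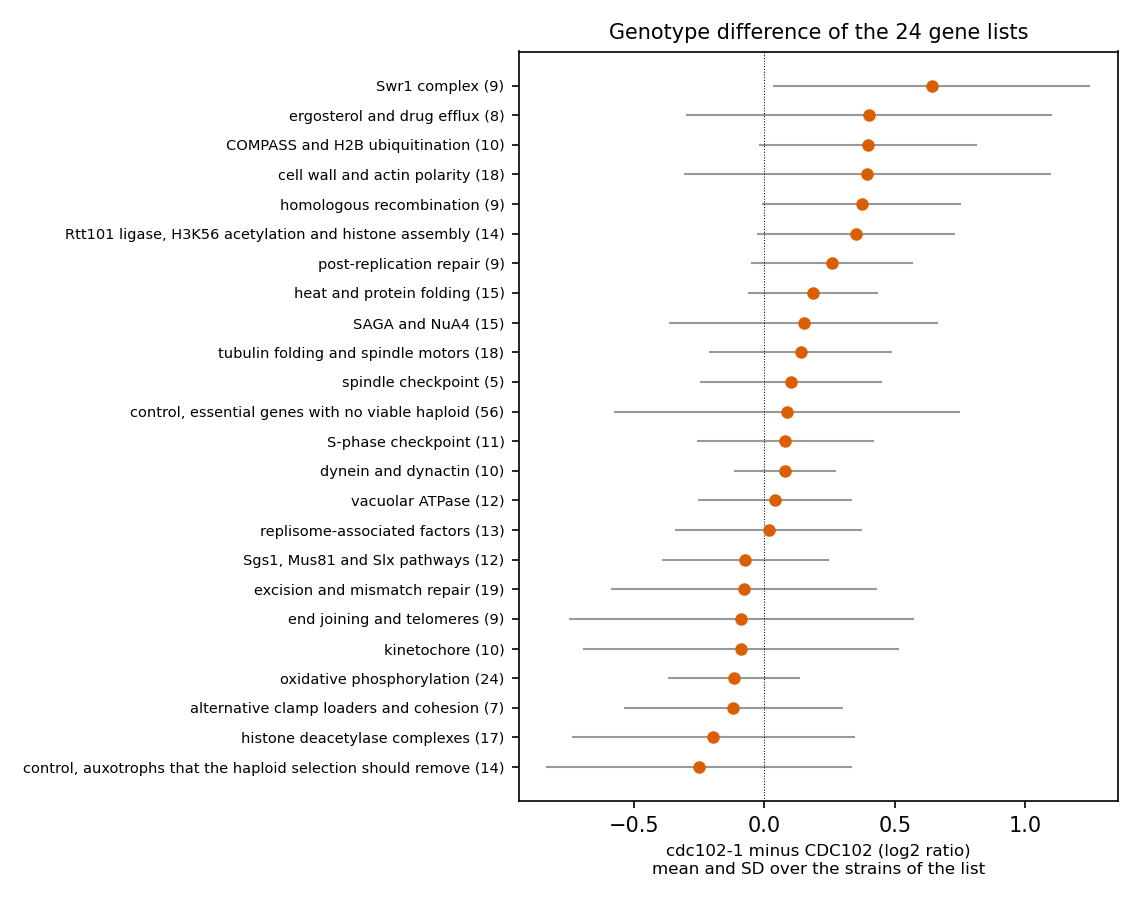
Mean difference in log2 ratio between the cdc102-1 and CDC102 pools (x axis) for the 24 gene lists (y axis, measured strains in brackets); points are means and bars are the SD over the strains of a list, not an error of the mean. The Swr1 complex has the highest mean (0.64) and the auxotroph control list the lowest (-0.25), and 0 lists passed the test.

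The comparison of 30 with 28 degree averages over both plasmids. The deletion of RLI1, an essential gene of ribosome recycling, had the largest higher ratio at 30 degree, by 2.83 ± 0.73 (SE), from 4.11 with cdc102-1 and 1.55 with CDC102. MMS22, a subunit of the Rtt101 ligase, was higher by 1.60 ± 0.35, PXR1 by 1.60 ± 0.60, YIH1 by 1.46 ± 0.28 and NCP1 by 1.43 ± 0.25. The lowest were GCV3, of the glycine cleavage system, at -2.66 ± 0.26, the open reading frame YCR050C at -2.60 ± 0.59, and the essential genes SPC105, of the kinetochore, at -2.53 ± 0.57, PRP9, a splicing factor, at -2.44 ± 0.76 and RNA14, of mRNA 3'-end processing, at -2.19 ± 0.56. None of these strains passed the test. With cdc102-1 and with CDC102 the differences were 2.12 and 1.09 for MMS22, 2.62 and 0.57 for PXR1, -1.57 and -3.50 for SPC105, -3.76 and -1.11 for PRP9, and -1.25 and -3.13 for RNA14. With the first tag only RLI1 differed by 1.52, PRP9 by -1.44 and RNA14 by -0.70, and RNA14 by -3.69 with the second. The tags of GCV3 and SPC105 disagreed as well. At 30 degree their plasmid differences were 3.59 and -2.74 for GCV3, and 4.74 and -1.12 for SPC105. Tags were averaged before the fit, so the SE does not measure such disagreement.

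In limma's test of the temperature term, 0 of 5288 strains passed, the smallest adjusted p was 0.730, and 295 strains had an unadjusted p under 0.05. Of these, 86 were higher and 209 lower at 30 degree, a split that became 154 higher and 160 lower with quantile normalization between arrays. Without the plasmid term the count was 220, and in fits to 3 arrays, which also lacked that term, it ran from 109 without the cdc102-1 array at 28 degree to 680 without the CDC102 array at 30 degree. Of the 24 lists, 1 passed by camera: the control list of essential genes averaged -0.38 ± 0.69 (SD over 56 strains) at an adjusted p of 0.0044, with 24 strains lower and 5 higher with both plasmids. Its largest members were RPT2 (-1.98 ± 0.24, SE) and CDC27 (-1.92 ± 0.22). The call was lost with an estimated correlation (adjusted p = 0.997) and with quantile normalization (mean -0.14, adjusted p = 0.630). On the 30 degree arrays 10.7% of that list's spots were missing, against 7.29% for the auxotroph control list and 2.93% for other named spots. The vacuolar ATPase list averaged 0.22 ± 0.30 with an adjusted p of 0.163.

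Genes near CDC102 address the direction of the ratio, since a deletion linked to the natMX insertion can be recovered less often together with it. The 44 strains within 50 kb of CDC102, by the coordinates of the reference gene table, had a median differing from the array's by -0.03, -0.01, -0.04 and -0.04 on the cdc102-1 arrays at 28 and 30 degree and the CDC102 arrays at 28 and 30 degree. Between 72.7% and 97.2% of the 4509 other windows of as many neighbouring strains lay as far from the median. The window's median thus showed no linkage on any array, and the direction stayed unsettled. That median pools all strains of the window, among them SMC3 and PSF2 of the essential-gene control list, so linkage of other strains could be masked. The deletion of PSF2 (CDC102) itself had ratios of -0.14, 0.04, 0.36 and 0.31. The adjoining JEM1, a chaperone gene, had ratios of 1.08, 0.60, 1.15 and 1.38, and its neighbour SMC3 had -1.50, -0.99, -1.32 and -1.04. On that side NET1 averaged -0.83 with CDC102, and on the other side ARG2, YJL070C and UTP18 averaged -0.89, 0.63 and -0.36. JEM1 and YJL070C (0.70, 0.14, 0.54 and 0.73) lay above the median on every array, as linkage gives if the ratio is Cy5 over Cy3. SMC3, NET1 and ARG2 lay below it on every array, and UTP18 had both signs. A strain without living haploids, such as SMC3, cannot show linkage. Whether this holds for NET1, ARG2 and UTP18 was not tested, so these neighbours do not settle the direction.

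**Figure D4:**
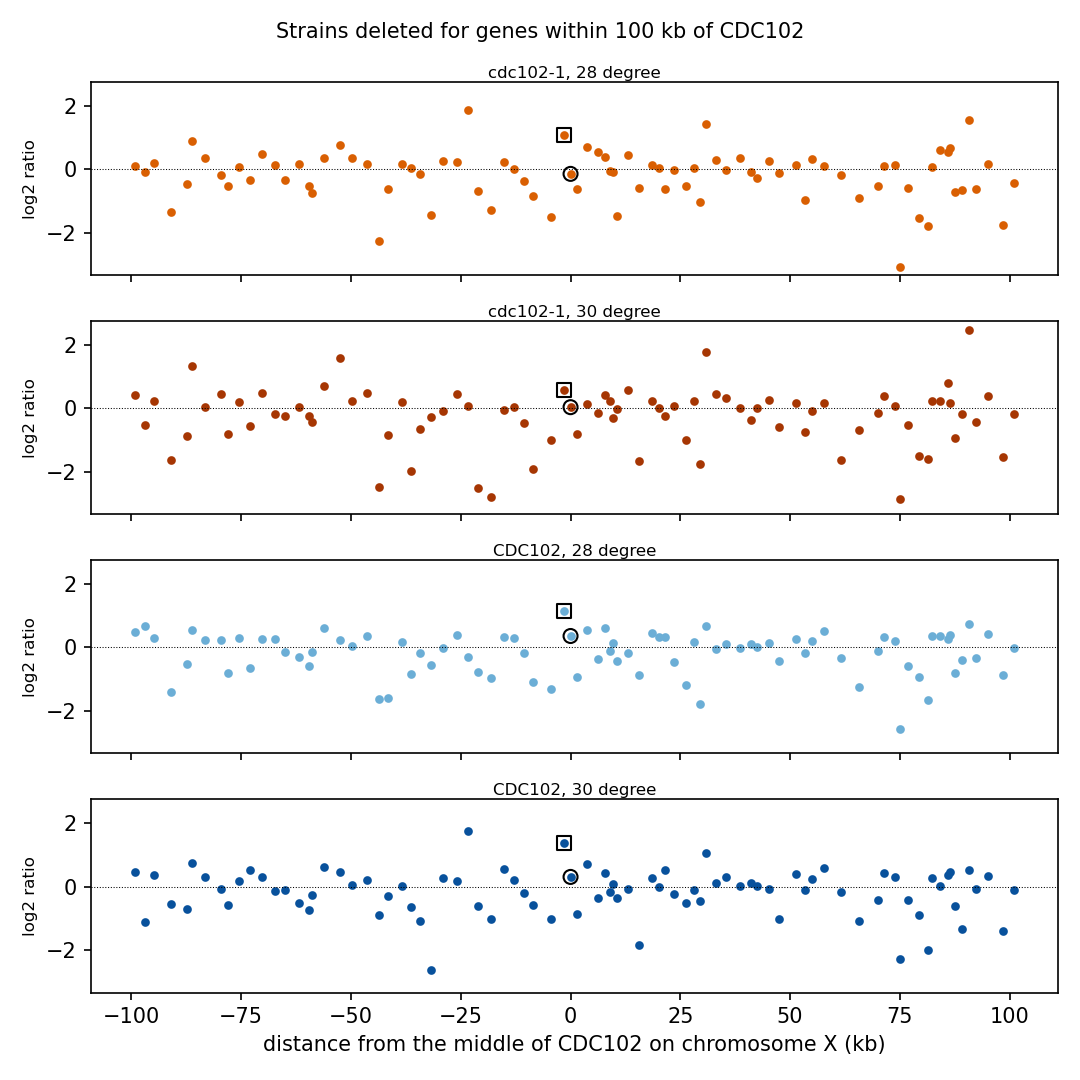
Centred log2 ratio (y axis) of deletion strains within 100 kb of CDC102 by distance from the middle of CDC102 on chromosome X (x axis, kb), 1 panel per array; each point is 1 strain, the circle marks PSF2 and the square JEM1. Points lie on both sides of 0 at all distances, and the 44 strains within 50 kb have medians between -0.04 and -0.01.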

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

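The unnamed spots and the opposite signs below were looked for by fixed rules, and all tests of explanations in this part were chosen after the results were seen. Among 1183 spots without a gene name that had a value on all arrays, 19 had a ratio higher by at least 1 with cdc102-1 at both temperatures and 14 a ratio lower by as much; which strains they belong to is not analysed here. The deletions PRP9 and QCR8 and the mean of the spindle checkpoint list had opposite plasmid differences at the 2 temperatures. With 1 array per combination, the difference between temperatures was not tested. The deletion of the splicing gene PRP9 differed by 1.18 at 28 degree and by -1.47 at 30 degree, where its tags read 1.17 and -4.11. The deletion of QCR8, a subunit of respiratory complex III, differed by -1.02 at 28 degree and by 1.85 at 30 degree. At 28 and 30 degree its ratios were 0.004 and 0.42 with cdc102-1, and 1.02 and -1.43 with CDC102. The spindle checkpoint list averaged -0.10 at 28 degree and 0.31 at 30 degree over 5 strains. Of these strains, 2 were higher and 2 lower at both temperatures, so the list's mean changed sign while most of its strains did not.

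Strains whose plasmid difference passed 1 in both tags at both temperatures, 25 higher and 8 lower, form a pattern open to follow-up. Independent noise of tags and arrays would give as many such strains in the plasmid-by-temperature contrast, built from the same tag differences, but the plasmid contrast held 4.71 times as many (5 and 2 strains in the former), which argues against it. Absence from both plates, with tags at background, is argued against for the 25 higher strains as a set, whose median ratio on the CDC102 arrays was 1.10 above that of the essential-gene list (0.20 against -0.90), but 4 of them (RIC1, TRP2, UTR1 and YAE1) lay at or below that list's median, and for those it stays open. For the 8 lower strains the gap was 0.30, with a 95% bootstrap interval of their median from -1.03 to 0.01, so background and a true difference cannot be told apart on so few strains. A difference in pool construction between both plasmids, which these arrays confound with genotype, stays open, as does a biological effect of cdc102-1, which may underlie the higher strains.

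The essential-gene control list was lower at 30 than at 28 degree, a call that was lost with quantile normalization. The SD over strains was larger at 30 than at 28 degree, at 1.03 against 0.73 with cdc102-1 and 0.77 against 0.65 with CDC102. Whether this wider spread accounts for the lower ratio was not tested. Signals near the background at 30 degree are a candidate explanation: 10.7% of the list's spots were missing there, 3.63 times the share of other named spots, and 0% at 28 degree. The auxotroph list also had missing spots, 7.29% at 30 degree and 0% at 28 degree. If every strain missing from the plates behaved like the essential-gene list, the auxotroph list would have lower ratios too. It averaged -0.12 with an SE over 14 strains of 0.23, against -0.38 with an SE of 0.09 over 56 essential-gene strains, which decides nothing. No biological explanation was tested for the essential-gene list.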

How the results depend on the processing

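List tests by tag and on tag-agreeing strains were added after the results were seen. The count of 0 strains for the plasmid held under every alternative run but 1: among the 3163 strains whose tags differed by under 1 on every array, 1 strain passed (GET2, adjusted p 0.036; smallest adjusted p elsewhere 0.179 to 0.999). Fewer strains were tested there, and the cause was not tested further. The count for temperature was 0 throughout. With 1 array left out, the lone array of a group is assumed to vary like the others, and the other factor was dropped as a term to keep a residual degree of freedom, so those values mix both factors. The plasmid count stayed 0, and unadjusted counts ran from 114 higher and 83 lower (without CDC102 at 30 degree) to 436 higher and 442 lower (without cdc102-1 at 28 degree). The signs of named strains are no check here, since the rule for naming them asked for one sign in both tags and at both temperatures.

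Of the lists, 3 passed for the plasmid without the temperature term (Swr1, Rtt101 and cell wall, adjusted p 0.039), 2 with the first tag only (Swr1 and COMPASS) and 2 on tag-agreeing strains (Swr1, SAGA and NuA4), and 0 with the second tag only; the cause was not tested. All these calls rest on the preset correlation: with an estimated one, 0 passed in the main setting and in each of those 3 settings (smallest adjusted p 0.522 to 0.804). For temperature the single list was lost (0) with an estimated correlation and with quantile normalization (0). Strains over the size at both temperatures numbered 227 higher and 154 lower at a 1.5-fold threshold, and 4 and 0 at a threshold of 2 on the log2 scale. With both tags over the main threshold of 1 they numbered 25 and 8. These counts change with the strictness of the threshold, as those thresholds imply. The mean linkage offset of -0.03 became -0.0799 within 25 kb, -0.0484 within 100 kb, -0.0896 with the first tag only and -0.0464 with the second tag only. Signal over background is unknown, and the 30 degree arrays had most missing spots.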

Other observations

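The test of trafficking members not yet seen was written before its result; the lists themselves and the other tests in this part were chosen after the leading strains were seen. Deletions across complexes that move proteins between the Golgi, endosomes and the vacuole had higher ratios with cdc102-1. The COG complex, a Golgi tether, averaged 1.00 ± 0.36 (SD) over 4 strains, with COG6 at 1.35 ± 0.29 (SE) and COG8 at 1.15 ± 0.24. The clathrin adaptors AP-1 and AP-3 averaged 0.89 ± 0.33 over 8 strains, with APS3 at 1.38 ± 0.37 and APM1 at 1.26 ± 0.32. Retromer, which returns receptors from endosomes to the Golgi, averaged 0.72 ± 0.44 over 5 strains, with VPS35 at 1.20 ± 0.21. The ESCRT complexes, which sort cargo into endosomal vesicles, averaged 0.69 ± 0.60 over 13 strains, 12 of them higher at both temperatures; VPS36 stood at 1.42 ± 0.34 and VPS20 at 1.07 ± 0.21, while VPS28 was the exception at -0.73 ± 0.37. The HOPS and CORVET tethers of the vacuole and endosome averaged 0.68 ± 0.23 over 8 strains, 7 higher at both temperatures, with VPS33 at 0.87 ± 0.20. The GARP tether averaged 0.63 ± 0.45 over 4 strains, Ypt6 with its exchange factor 1.14 ± 0.92 over 3, Arl1 and Arl3 with their partners 1.07 ± 0.76 over 5 and the GET pathway 1.63 ± 1.16 over 5. These means include leading strains that prompted the lists. Without those, the unseen members averaged 0.51 for the GET pathway (2 strains), 0.62 for Ypt6 (2), 0.55 for Arl1 and Arl3 (3), 0.42 for GARP (3), 0.47 for the ESCRT complexes (10), 0.72 for retromer (4) and 0.69 for HOPS and CORVET (7), while no member of COG, AP-1 or AP-3 had been seen.

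Other strains that passed the size in both tags at both temperatures, chosen after their values were seen, included SPF1, an endoplasmic reticulum ATPase (1.59 ± 0.28), SAC1, a phosphoinositide phosphatase (1.49 ± 0.21), and LTE1, of mitotic exit (1.58 ± 0.22). Casein kinase 2 averaged 0.60 ± 0.73 over 4 strains, between CKB2 at 1.42 ± 0.20 and CKA2 at -0.35 ± 0.21. Negative regulators of Ras and protein kinase A averaged 0.23 ± 0.96 over 5 strains, with the paralogs IRA1 and IRA2 at 1.46 ± 0.22 and -0.95 ± 0.24. IPT1, of sphingolipid synthesis, was lower by this rule (-1.54 ± 0.21).

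A hypothesis from these data is that deletions of Golgi and endosome trafficking genes, tested together with the GET pathway of the endoplasmic reticulum, are recovered differently with cdc102-1. Of 43 members of the 9 lists whose values had not been seen, 41 were tested, leaving out VPS53 and APS3 within 100 kb of CDC102: their mean difference was 0.66 (SD 0.39), 0.55 at 28 degree and 0.78 at 30 degree, against 0.01 for other strains, and 36 were higher and 1 lower at both temperatures. A permutation test over strains gave p = 1e-05, the smallest that 100000 resamples can give. It describes these arrays, since strains share them and are not replicates, and it allows for no correlation between strains. The set was not run with quantile normalization, with single tags or with an estimated correlation. Quantile normalization lowered the means of the Swr1 and COMPASS lists, and no list passed for the plasmid with an estimated correlation. The 39 members outside the GET pathway averaged 0.67 (34 higher and 1 lower), a check added later. Slow growth of the deletion strains as the cause was not settled. The higher mean of the vacuolar ATPase and oxidative phosphorylation lists, both taken to be of slow-growing strains, was 0.0415. Those lists were thus not higher with cdc102-1. Growth was not measured here, and this comparison was chosen after the results were seen, so it cannot decide the question. Sensitivity to Nat plates with either plasmid, stronger in the cdc102-1 pools, cannot be told apart from an effect of the allele: on the CDC102 arrays these members had a median only 0.0518 above that of 268 members of the 22 other lists (0.11 against 0.06, one-sided permutation p = 0.217), and pool and plate conditions go with the plasmid, so the class may reflect either.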
